A study of Oryctolagus cuniculus with 12 samples.

How the data were processed

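Total RNA of the rabbit basilar artery was extracted with TRIzol and labelled with a low-input kit for single-colour (Cy3) arrays, per the labels. There were 12 arrays on 3 slides, with 3 arrays in each of the 4 groups control, day 3, day 5 and day 7. Each replicate number is 1 slide, and each slide holds 1 array per group.

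The authors deposited the scanner output of each array, made with Agilent Feature Extraction 9.5.1.1. Per the file headers, the processed signal is an intensity that was background-subtracted and detrended within its array, with a positive surrogate value near background and no scaling between arrays. The mean signal of a spot and the median signal of its local background are raw intensity values per the file headers. The flags for spots well above background, outlier spots and saturated spots are of the kind other, values of 0 or 1 per spot per the file headers. The authors' value table holds an intensity on a linear scale, quantile-normalized between the 12 arrays: every column was checked to have the same median, 27.0, and its log2 values followed the processed signals (r of at least 0.994). It was used here as an alternative only.

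For the tests, control spots were left out, spots with an outlier flag were set to missing, the log2 processed signal was taken relative to the 75th percentile of the non-control spots of its array, and the spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 26434 of 43623 probes. Probes were named from the accessions, gene identifiers, symbols and descriptions the arrays give, using a RefSeq gene table of assembly mOryCun1.1 for names only: 23018 probes had 1 gene, 103 several and 20502 none, and no coordinates are given because the array names no genome build. Array descriptions differed from the table's name for some genes named here: IL1RN was described as an interleukin-1 receptor, C1R as similar to MASP1, LRRC17 as similar to a slit protein and SAA3 as a pseudogene.

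Each day was compared with the controls, the days with each other, and the mean of the 3 days with the controls, in 1 fit of all 12 arrays with limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table), two-sided, without a block. Probes were called at a Benjamini-Hochberg adjusted p below 0.05, and an F test asked for any difference between a day and the controls. A gene's value is that of its tested probe with the highest mean. Of 3411 genes with several tested probes, 0 had calls in both directions against the controls. Among called genes with several probes, every probe was called for 142 of 235 on day 3, 46 of 77 on day 5 and 51 of 89 on day 7. Where no array of a group was well above background, the fold is a bound, given as at least the mean of the brighter group over the mean, in the dim group, of the higher of the array's lowest signal well above background and the probe's own signal. The 31 gene lists for cell types and pathways were tested with camera at a preset correlation of 0.01 on 7355 genes, 1 probe per gene, with adjustment over the 27 lists of at least 5 measured members; 27 genes with a missing spot were left out. Some genes belong to several lists. C1QB is in macrophage and complement, MSR1 in macrophage and lipid uptake, and CTSS in macrophage and antigen presentation. LUM is in dedifferentiated smooth muscle and fibroblasts and leptomeninges, and MYL9 in contractile smooth muscle and calcium sensitization. The calls of such lists are therefore not separate evidence. With an estimated correlation, calls held for cell cycle on day 3 and for macrophage, cell cycle and complement on day 5, and for none on day 7. List medians and list tests use the fitted changes, those of such dim genes included, and setting these genes to their bound moved a list median by at most 0.884, for cell cycle on day 3. On data simulated with known changes, the test recovered 40% of 2-fold and 87% of 4-fold changes for day 3, 38% and 90% for day 5, and 45% and 90% for day 7, with 6, 10 and 5 wrong calls among 26325 probes, and the list test called the 1 changed list and 0 of the unchanged lists. The simulated noise was independent between probes and arrays. It therefore does not show how the preset correlation behaves where the genes of a list vary together.

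The comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule names, for each day, up to 10 rises and 10 falls with the largest log2 change among called genes whose arrays do not overlap between groups, up to 4 called members of each list or, with none called, 2 with the smallest p as values, and 24 fixed genes of vasospasm. Of these, CNN1, F2R and AGTR1 had no named probe and ICAM1 was not above background. Up to 5 genes per direction were named between days by the first part of the rule. Which of the named genes are described was decided after their values were seen, by whether the call held without each array: 47 of 81 called genes on day 3, 25 of 46 on day 5 and 22 of 51 on day 7.

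The alternatives were normexp background correction (offset 50), quantile normalization, centring on the median, no filter on dim probes, a filter for all 12 arrays, the slide as a block, only the 6 arrays compared, an intensity trend with a robust prior, array weights, the authors' table, a 2-fold minimum, an adjusted p below 0.01, outlier spots kept, and leaving out each array. For lists they were an estimated correlation, fry, the mean of a gene's probes, quantile normalization, normexp, the slide as a block and leaving out each array. To see what the shared controls alone give, changes were also computed in 20 simulated data sets with no effect and with the same spread of a probe in every group.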

Results

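RNA of the rabbit basilar artery, the vessel that runs along the brain stem, was measured on 12 single-colour Agilent arrays, 1 array per sample. The samples fall into 4 groups of 3: controls, called day 0 in the series, and arteries taken 3, 5 and 7 days after an experimental subarachnoid hemorrhage, a bleed into the fluid-filled space around the brain. The series asks which genes in the artery change over these days, in which cerebral arteries often narrow. Each array carried 43623 non-control probes, of which 26434 were tested, and the tested probes named 7382 genes. The 75th percentile of the signal lay between 127 and 191 units over the 12 arrays, and no spot was saturated. The number of arrays, 3 per group, limits the precision. Every p-value here measures only the spread between these samples, which may be technical, because the labels do not say that the samples of a group are separate animals.

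Control replicate 2 stood apart from the other arrays in its quality values. Across probes, which are not independent replicates, the correlation between arrays of a group was 0.964 to 0.978 in the controls, 0.979 to 0.987 on day 3, 0.973 to 0.986 on day 5 and 0.982 to 0.985 on day 7. Arrays of different groups correlated as highly in places, as day 5 replicate 1 and day 7 replicate 1 (0.988). On control replicate 2, 50.1% of the spots were well above background, against 58.2% to 64.0% on the other arrays, and 169 spots had an outlier flag, against 1 to 16. It was not the only array with a low weight in the alternative with array weights. Its weight was 0.461, against 0.327 for day 5 replicate 3 and 0.384 for control replicate 3. The other arrays of slide 3 had 0.525 on day 3 and 0.648 on day 7. Each of the 3 slides held 1 array of every group, and each group had the same position on all 3 slides, so position and group cannot be told apart.

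**Figure D1:**
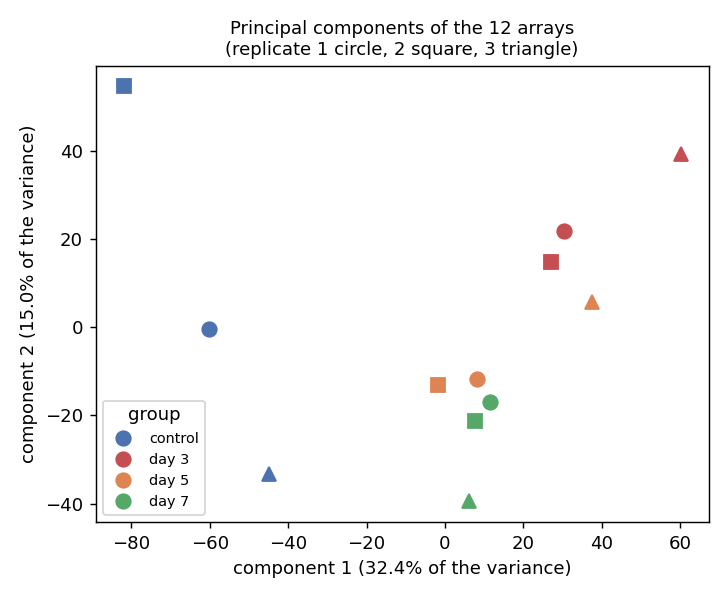
Each of the 12 arrays by its first and second principal component of the tested probes, which hold 32.4% and 15.0% of the variance; colours stand for the 4 groups and symbols for the replicate, which is also the slide. The 3 controls lie at lower values of the first component than the arrays after the bleed, and control replicate 2 lies far from the other controls on the second.

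On day 3 after the bleed, SAA3 and HP had the largest rises of the named genes, and the cell cycle list had the smallest adjusted p of the lists tested. SAA3, an acute-phase serum amyloid A, rose 59.6-fold, from 3.01 ± 1.16 to 8.91 ± 0.48 (SD, n = 3 each) on the log2 scale relative to the 75th percentile of the array. HP, haptoglobin, which binds free hemoglobin, rose 54.2-fold, from 0.56 ± 1.13 to 6.32 ± 0.34 (SD, n = 3 each). HMOX1, heme oxygenase 1, which breaks down heme, rose 13.1-fold, from -2.48 ± 0.39 to 1.24 ± 0.82 (SD, n = 3 each; above background in 2 of 3 controls). Lists of cell division, macrophage, complement and interferon genes rose, and the list of contractile smooth muscle genes fell. With an estimated correlation only the cell cycle list kept its call (adjusted p = 0.0384), against 0.0827, 0.109, 0.135 and 0.168 for the other 4.

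SAA3 rose by 5.90 (SE 0.52, limma adjusted p = 0.000134), with 5.82, 6.74 and 5.13 on the 3 slides. HP rose by 5.76 (SE 0.55, adjusted p = 0.000174), with 6.34, 6.11 and 4.84. LOC100009168, named serum amyloid protein A, rose by 5.58 (SE 0.61, adjusted p = 0.000402). CCK, the precursor of the peptide hormone cholecystokinin, rose by 4.88 (SE 0.46, adjusted p = 0.000165), and CRYBA4, a lens crystallin, by 4.61 (SE 0.48, adjusted p = 0.000292); 2 of 3 controls measured each. LOC100344919, named vascular non-inflammatory molecule 3-like, rose by 4.93 (SE 0.76, adjusted p = 0.00332; 2 of 3 controls measured it), and LOC100346285, a granzyme A-like protease gene, by 4.17 (SE 0.31, adjusted p = 7.21e-05). NCAPG, a condensin subunit that packs chromosomes, was at least 3.59-fold higher (adjusted p = 7.74e-05) and BUB1B, a spindle checkpoint kinase, at least 6.02-fold higher (adjusted p = 5.84e-05); no control measured either gene well above background. HMOX1 rose by 3.71 (SE 0.37, adjusted p = 0.000211), with 2.77, 3.93 and 4.43 on the slides.

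Of 29 measured cell cycle genes, 19 rose and 1 fell on day 3 (23 and 1 adjusted over the list alone). The list rose with a median log2 change of 1.75 (camera adjusted p = 2.72e-18, then adjusted p = 0.0384 with an estimated correlation and 3.91e-16 with the slide as a block). Its median was 1.02, 1.69 and 1.52 within the slides. For 9 members no control was well above background, and with these at their bound the median was 0.86. Bounds in the same way gave 1.22 for the macrophage list, 0.85 for complement, 0.92 for cytokines and chemokines, 0.65 for lymphocyte genes and 0.24 for matrix proteases and inhibitors. CDK1, the kinase that drives entry into mitosis, rose 11.9-fold (adjusted p = 0.000116; 2 of 3 controls measured it). RRM2, a subunit of the enzyme that makes DNA precursors, was at least 3.29-fold higher (adjusted p = 0.000144). The member that fell was CCND1, cyclin D1 of the G1 phase, at -0.81 (adjusted p = 0.0369), a gene named after its value was seen. Its call ended without control replicate 2 (adjusted p = 0.103), control replicate 3 (0.0703), day 3 replicate 1 (0.0803), day 3 replicate 2 (0.129), day 5 replicate 2 (0.0545) and day 7 replicate 2 (0.0547).

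Among immune genes on day 3, 7 of 12 macrophage genes rose and none fell (11 and 0 adjusted over the list alone), 6 of 15 complement genes rose (12 adjusted over the list alone) and 6 of 11 interferon response genes rose (11 adjusted over the list alone). The macrophage list rose with a median of 1.35 (slides 1.03, 1.49 and 1.36; adjusted p = 6.25e-09, then adjusted p = 0.0827 with an estimated correlation and 7.13e-09 with the slide as a block). CD68, a lysosomal protein of macrophages, rose 4.49-fold (adjusted p = 0.000126). CD14, a receptor for bacterial lipopolysaccharide, rose 2.72-fold (adjusted p = 0.00291). The complement list rose with a median of 0.91 (slides 0.74, 1.20 and 1.07; adjusted p = 5.03e-08, then adjusted p = 0.109 with an estimated correlation and 1.07e-07 with the slide as a block). C1R, a protease of the first complement component, rose 4.10-fold (adjusted p = 7.74e-05). CFB, factor B of the alternative pathway, rose 2.86-fold (adjusted p = 0.00469). The interferon list rose with a median of 1.38 (slides 1.18, 1.90 and 1.05; adjusted p = 1.78e-08, then adjusted p = 0.135 with an estimated correlation and 1.9e-07 with the slide as a block). XAF1, an interferon-induced gene linked to cell death, rose 7.07-fold (adjusted p = 0.00988; 1 of 3 controls measured it). Without control replicate 2, all 9 list results for macrophage, complement and cell cycle genes on the 3 days were still called higher.

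Of 13 genes of heme, iron and oxidative stress, 6 rose and 1 fell on day 3 (9 and 1 adjusted over the list alone). The list rose with a median of 0.90 (slides 0.78, 1.14 and 0.96; adjusted p = 1.51e-06, then adjusted p = 0.109 with an estimated correlation and 1.82e-06 with the slide as a block). CP, the ferroxidase ceruloplasmin, rose 7.37-fold (adjusted p = 7.74e-05). GCLM, a subunit of the first enzyme of glutathione synthesis, rose 3.55-fold (adjusted p = 0.00045). The member that fell, TFRC, the transferrin receptor through which cells take up iron, was named after its value was seen and changed by -1.03 (adjusted p = 0.0446); without each array other than day 3 replicate 1 the adjusted p was 0.0511 to 0.161.

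Of 15 cytokine and chemokine genes, 6 rose on day 3 (7 adjusted over the list alone), with a list median of 1.12 (slides 1.91, 0.95 and 0.93; adjusted p = 2.33e-05, then adjusted p = 0.135 with an estimated correlation and 5.51e-05 with the slide as a block). CCL2, which attracts monocytes, rose 5.80-fold (log2 change 2.54, SE 0.46, adjusted p = 0.00803). IL1RN, the interleukin-1 receptor antagonist, rose 3.92-fold (adjusted p = 0.00196). IL10, an anti-inflammatory cytokine, was at least 2.72-fold higher (adjusted p = 0.00163), with no call after normexp background correction. IL6, an inflammatory cytokine, was at least 1.61-fold higher (adjusted p = 0.0169), a call that ended without control replicate 1 (adjusted p = 0.0584) and without day 3 replicate 3 (0.0535). Of 25 extracellular matrix genes, 6 rose (14 and 1 lower adjusted over the list alone), with a list median of 0.48 (slides 0.67, 0.33 and 0.83; adjusted p = 2.33e-05, then adjusted p = 0.193 with an estimated correlation). COL1A1, a chain of fibrillar collagen, rose 2.95-fold (adjusted p = 0.00254). Of 19 matrix proteases and inhibitors, 5 rose (7 and 3 lower adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0169, then adjusted p = 0.193 with an estimated correlation). That list had no call with the slide as a block (adjusted p = 0.0511) or without control replicate 3 (0.143). TIMP1, an inhibitor of matrix metalloproteinases, rose 11.2-fold (adjusted p = 7.74e-05). PLAU, the urokinase plasminogen activator, rose 2.86-fold (adjusted p = 0.00163).

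Further lists with few called members rose on day 3. Antigen presentation had a median of 1.06 with 1 of 10 members called (7 adjusted over the list alone; adjusted p = 0.000441, then adjusted p = 0.298 with an estimated correlation). The unfolded protein response, which acts on misfolded proteins, had 0.42 with 2 of 12 called (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.0136, then adjusted p = 0.31 with an estimated correlation; 0.0972 without day 3 replicate 3). PDIA4, a protein disulfide isomerase of that list, rose 2.14-fold (adjusted p = 0.00489). Lymphocyte genes had 0.74 with 1 of 10 called (2 adjusted over the list alone; adjusted p = 0.0151, then adjusted p = 0.283 with an estimated correlation; 0.0721 without control replicate 3, 0.0525 without day 3 replicate 3 and 0.133 after normexp background correction). CD79B, part of the B cell receptor, was at least 1.75-fold higher (adjusted p = 0.00708).

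The named falls on day 3 included genes for transporters of organic anions. SLC22A6, an organic anion transporter, fell by 2.56 on the log2 scale (SE 0.42, adjusted p = 0.00514), with -3.00, -1.98 and -2.70 on the slides. SLC22A8, a related transporter, fell by 3.24 (SE 0.66, adjusted p = 0.0149), a call that ended without day 3 replicate 2 (adjusted p = 0.0504). SLCO1A2, another organic anion transporter, was at least 1.53-fold lower (adjusted p = 0.00721; 2 of 3 controls and no day 3 array measured it). PTGDS, which makes prostaglandin D2 and is abundant in the leptomeninges, the thin membranes around the brain, fell by 1.59 from a high level (10.33 ± 0.56 to 8.74 ± 0.16, SD, n = 3 each; adjusted p = 0.0029). IL13RA2, a receptor of interleukin 13, was at least 4.36-fold lower (adjusted p = 0.0061), with no call after normexp background correction, and SCG5, a neuroendocrine secretory protein, was at least 2.85-fold lower (adjusted p = 0.00287; 2 of 3 controls measured it). CSPG5, a proteoglycan of nervous tissue, fell by 2.77 (SE 0.49, adjusted p = 0.00745; 2 of 3 day 3 arrays measured it).

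Lists of the contractile machinery fell on day 3, with small changes per gene. Of 25 contractile smooth muscle genes, 2 fell and 23 had no call (0 higher and 2 lower adjusted over the list alone), and 2 of 25 had a positive change. The median was -0.45 (slides -0.37, -0.54 and -0.46; adjusted p = 2.33e-05, then adjusted p = 0.168 with an estimated correlation and 7.45e-06 with the slide as a block). ACTA2, smooth muscle actin, changed by -0.69 (adjusted p = 0.142) and MYH11, smooth muscle myosin, by -0.84 (adjusted p = 0.121). Of 28 ion channel and calcium handling genes, 3 fell (3 adjusted over the list alone), with a median of -0.24 (slides -0.34, -0.33 and -0.36; adjusted p = 0.00938, then adjusted p = 0.109 with an estimated correlation). RYR3, a calcium release channel, fell by 1.11 (SE 0.17, adjusted p = 0.00286). Of 20 calcium sensitization genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0151, then adjusted p = 0.193 with an estimated correlation; 0.0619 after normexp background correction). Of 10 endothelial genes, 1 fell, with a median of -0.57 (adjusted p = 0.0169, then adjusted p = 0.298 with an estimated correlation; 0.0526 without control replicate 1). That gene, KDR, the main receptor of vascular endothelial growth factor, was at least 2.31-fold lower (adjusted p = 0.0162; 2 of 3 controls and no day 3 array measured it; 0.0725 without day 3 replicate 3).

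Genes of vasoconstriction showed few calls on day 3, and the remaining lists had none as lists. EDNRA, the endothelin receptor of smooth muscle, changed by 0.08 (SE 0.15, adjusted p = 0.813), EDN1, endothelin 1, by -0.26 (adjusted p = 0.613), NOS3, endothelial nitric oxide synthase, by -0.79 (adjusted p = 0.176) and SPP1, osteopontin, by 2.47 (SE 0.73, adjusted p = 0.0692). The list of vasoconstrictor systems had 1 of 15 members called higher (adjusted p = 0.74) and that of vasodilator systems 2 of 19 (adjusted p = 0.819). The vasoconstrictor gene called was HTR2A, a fixed gene, with log2 changes of 1.095, 1.09 and 2.434 on the slides. Its call ended without 9 of the 12 arrays in turn (limma adjusted p = 0.052 to 0.132). No call was made for the lists of dedifferentiated smooth muscle (4 of 11 higher; adjusted p = 0.111), fibroblasts and leptomeninges (1 higher and 2 lower of 11; adjusted p = 0.711), skeletal muscle (1 of 5 lower; adjusted p = 0.102), neutrophils (0 of 8; adjusted p = 0.562), glycolysis and hypoxia (2 of 21 higher; adjusted p = 0.32) or oxidative phosphorylation (1 of 21 lower; adjusted p = 0.364). Nor was one made for TGF-beta and BMP signalling (2 higher and 5 lower of 18; adjusted p = 0.128), immediate early and heat shock genes (1 of 15 higher; adjusted p = 0.255), cholesterol synthesis (1 of 12 higher; adjusted p = 0.0561) or lipid uptake and efflux (2 higher and 1 lower of 13; adjusted p = 0.103). Some of these lists had a call in other settings: dedifferentiated smooth muscle with fry (adjusted p = 0.0261) and normexp (0.0431), skeletal muscle with fry (0.0113), and cholesterol synthesis with quantile normalization (0.0491) and with the mean of all probes of a gene (0.0448). The neutrophil list had a median of -0.06 and a mean of 0.01. BMP4, a growth factor of the BMP family, fell by 1.23 (adjusted p = 0.00335), LDHA, lactate dehydrogenase A, rose 2.99-fold (adjusted p = 0.00137) and PTGER4, a prostaglandin E2 receptor, had a change of 0.93 (adjusted p = 0.0207, and 0.0603, 0.0658 and 0.0895 without control replicate 2, day 3 replicate 2 and day 3 replicate 3). The lists of activated endothelium (3 measured), erythroid (3), neural and glial (4) and peripheral nerve genes (2) were too small to test, and 0 of their members were called. HBA, an alpha globin of red blood cells, changed by 0.17 (adjusted p = 0.884).

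In total 1754 probes changed on day 3, 1245 higher and 509 lower (limma, adjusted p below 0.05, two-sided), naming 515 genes, 363 higher and 152 lower. Within the slides, 1748 of the 1754 probes had the same direction on all 3 slides, and so did all 81 called named genes. The calls were made on these same arrays, and part of the named genes were chosen for arrays that do not overlap. Such agreement was therefore largely set by the selection. The count of called probes was 979 without control replicate 1, 1110 without day 3 replicate 2 and 789 without day 3 replicate 3. It was 1007 with normexp background correction, 974 with no filter on dim probes and 897 on the 6 arrays compared alone. With normexp background correction the log2 change was 0.81 for NCAPG, 0.97 for BUB1B, 2.36 for HMOX1, 2.79 for CCK, 2.54 for LOC100344919, 1.69 for CDK1, 1.02 for XAF1, 1.16 for GCLM and -1.05 for CSPG5. Calls ended with it for RRM2 (adjusted p = 0.0634), CD79B (0.43), IL10 (0.112), IL6 (0.433), IL13RA2 (0.0687), SLCO1A2 (0.0989), SCG5 (0.237) and KDR (0.245). IL6 and KDR also had no call on the 6 arrays alone (0.0689 and 0.0625), and with fry the lists of endothelial and antigen presentation genes had none (0.058 each).

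**Figure D2:**
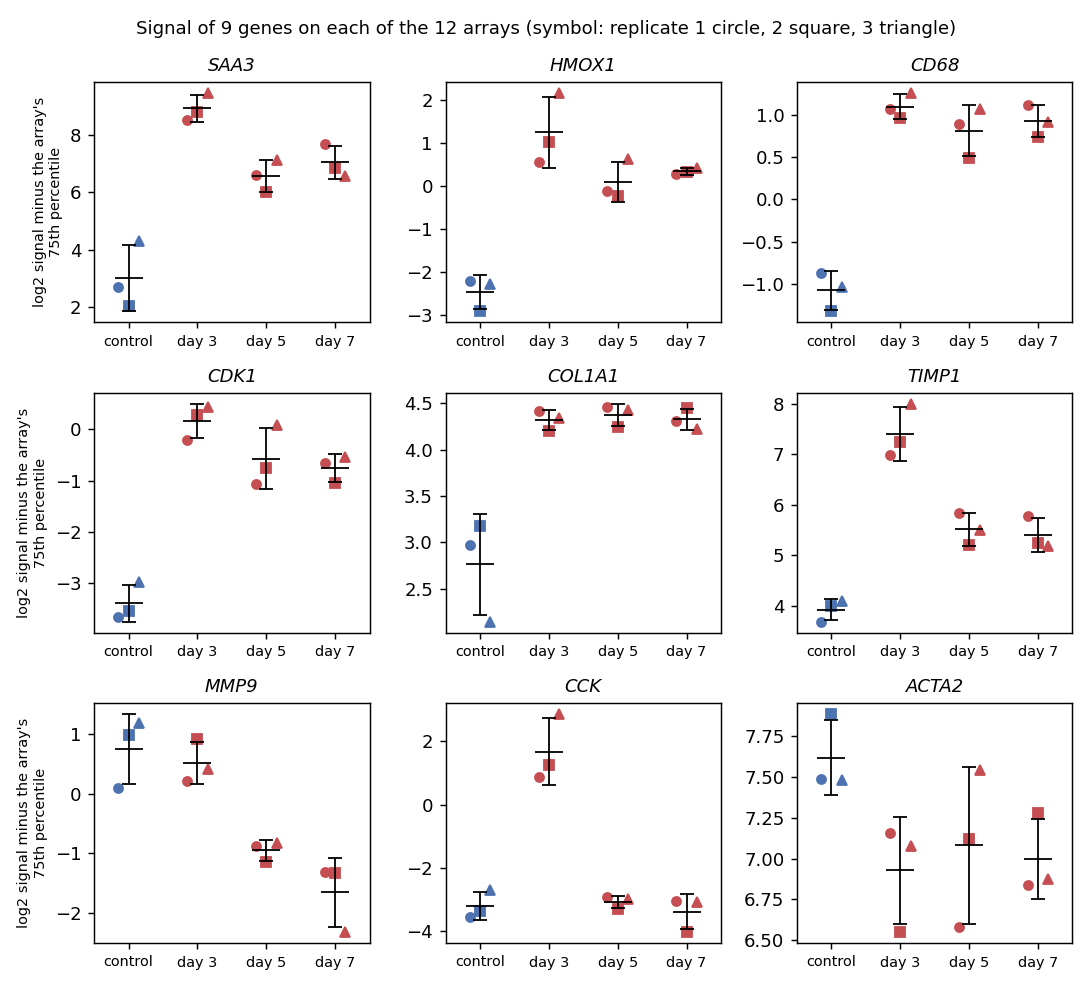
Log2 signal relative to the 75th percentile of the array for the named genes shown, with 1 symbol per array, the group mean as a line and error bars of 1 SD (n = 3 per group). SAA3 has a mean of 3.01 in the controls and of 8.91, 6.56 and 7.04 on days 3, 5 and 7, and MMP9 has 0.76 in the controls and -1.66 on day 7.

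On day 5, which asks the same question 2 days later, macrophage, cell cycle and complement genes had the smallest adjusted p of the lists that rose, and SAA3, HP and HMOX1 were again higher than in the controls. SAA3 rose 11.7-fold, to 6.56 ± 0.55 from 3.01 ± 1.16 (SD, n = 3 each), and HP rose 10.2-fold, to 3.91 ± 0.87 from 0.56 ± 1.13. CRYBA4 rose 17.3-fold and SLC15A2, a peptide transporter, 11.3-fold. Among the named falls was RSPO1, a secreted activator of Wnt signalling, which fell by 1.67 on the log2 scale.

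The largest rises on day 5 with a call that held without each array were CRYBA4 (log2 change 4.11, SE 0.48, adjusted p = 0.00166), SAA3 (3.55, SE 0.52, adjusted p = 0.00519), SLC15A2 (3.503, SE 0.46, adjusted p = 0.00287), HP (3.35, SE 0.55, adjusted p = 0.0102) and ABCA6, a lipid transporter of the ABC family (3.25, SE 0.49, adjusted p = 0.00619); genes with such calls were preferred as examples after the values were seen. On the 3 slides SAA3 changed by 3.90, 3.95 and 2.80, and ABCA6 by 2.69, 2.58 and 4.48. CRYBA4 and SLC15A2 were each measured in 2 of 3 controls. SGPL1, which breaks down sphingosine 1-phosphate, was at least 2.35-fold higher (adjusted p = 0.00283) and NCAPG at least 1.85-fold higher (adjusted p = 0.00106), with no control well above background for either. RLN1, a relaxin hormone, had the largest rise, 4.69 (SE 0.98, adjusted p = 0.0341). Its call ended without control replicate 1 (adjusted p = 0.112), control replicate 2 (0.11), day 3 replicate 1 (0.0506), day 5 replicate 2 (0.0902), day 5 replicate 3 (0.109) and day 7 replicate 2 (0.0544).

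Of 12 macrophage genes, 8 rose on day 5 (11 adjusted over the list alone), with a list median of 1.67 (slides 1.43, 1.85 and 1.90; adjusted p = 5.85e-14, then adjusted p = 0.038 with an estimated correlation and 3.78e-13 with the slide as a block). CD68 rose 3.69-fold (adjusted p = 0.00106), MRC1, the mannose receptor of macrophages, rose 3.57-fold (adjusted p = 0.00918). MPEG1, a pore-forming protein of macrophages, was at least 3.29-fold higher (adjusted p = 0.0014). Of 29 cell cycle genes, 10 rose (17 and 1 lower adjusted over the list alone), with a median of 0.84 (slides 0.90, 0.87 and 0.95; adjusted p = 3.78e-13, then adjusted p = 0.038 with an estimated correlation and 5.47e-12 with the slide as a block). With the 8 members that no control measured well above background at their bound, the cell cycle median was 0.58, and bounds gave 1.08 for complement and 0.27 for lymphocyte genes. CDK1 rose 7.10-fold (adjusted p = 0.00125) and NDC80, a kinetochore protein, 4.85-fold (adjusted p = 0.00105), each measured in 2 of 3 controls. Of 15 complement genes, 8 rose (13 and 1 lower adjusted over the list alone), with a median of 1.13 (slides 1.14, 1.40 and 1.27; adjusted p = 1.12e-12, then adjusted p = 0.038 with an estimated correlation and 5.99e-12 with the slide as a block). C1R rose 3.64-fold (adjusted p = 0.000676). Of 11 interferon response genes, 5 rose (11 adjusted over the list alone), with a median of 1.38 (slides 0.99, 1.25 and 1.93; adjusted p = 7.13e-11, then adjusted p = 0.094 with an estimated correlation and 3.31e-09 with the slide as a block). Of 13 genes of heme, iron and oxidative stress, 5 rose (7 and 1 lower adjusted over the list alone), with a median of 0.67 (slides 0.59, 0.72 and 0.82; adjusted p = 7.5e-06, then adjusted p = 0.11 with an estimated correlation and 7.01e-06 with the slide as a block). HMOX1 rose 5.89-fold (adjusted p = 0.00484) and CP 3.85-fold (adjusted p = 0.00166).

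Other lists rose on day 5 with few members called. Extracellular matrix genes had a median of 0.36 with 2 of 25 called (4 adjusted over the list alone; adjusted p = 0.000104, then adjusted p = 0.307 with an estimated correlation). Their call ended without control replicate 3 (0.0526) and after normexp background correction (0.17). The members called were COL1A1, which rose 3.07-fold (adjusted p = 0.00453), and COL1A2, the other chain of type I collagen, which rose 2.73-fold (adjusted p = 0.00619). Antigen presentation had a median of 1.04 with 0 of 10 called (2 adjusted over the list alone; adjusted p = 0.000789, then adjusted p = 0.312 with an estimated correlation; 0.0716 without day 5 replicate 3; slides -0.005, 1.497 and 1.723). Lymphocyte genes had 0.58 with 0 of 10 called (2 adjusted over the list alone; adjusted p = 0.0452, then adjusted p = 0.312 with an estimated correlation); without control replicate 1, control replicate 3 or day 5 replicate 3 the adjusted p was 0.0506, 0.183 or 0.437. Cytokines and chemokines had 0.72 with 1 of 15 called (adjusted p = 0.0482, then adjusted p = 0.376 with an estimated correlation). That call ended without control replicate 1 (0.46), control replicate 3 (0.0526), day 5 replicate 3 (0.257) and day 7 replicates 1, 2 and 3 (0.053, 0.0511 and 0.0507).

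Among lower values on day 5, RSPO1 fell by 1.67 (SE 0.21, adjusted p = 0.00206; slides -1.69, -1.43 and -1.90), TENM1, a teneurin of the cell surface, fell by 1.65 (SE 0.28, adjusted p = 0.0106) and RGCC, a regulator of the cell cycle, fell by 1.92 (SE 0.27, adjusted p = 0.00407; 2 of 3 controls and 1 of 3 day 5 arrays measured it). The contractile smooth muscle list fell with a median of -0.34 and 0 of 25 members called, also adjusted over the list alone (slides -0.46, -0.20 and -0.17; adjusted p = 2.04e-05, then adjusted p = 0.18 with an estimated correlation and 7.98e-06 with the slide as a block). ACTA2 changed by -0.54 (adjusted p = 0.376) and MYH11 by -0.69 (adjusted p = 0.312). Ion channels and calcium handling had a median of -0.20 with 0 of 28 called (adjusted p = 0.00198, then adjusted p = 0.0658 with an estimated correlation). Endothelial genes had -0.44 with 0 of 10 called (adjusted p = 0.0295, then adjusted p = 0.312 with an estimated correlation; 0.139 without control replicate 1 and 0.121 without day 5 replicate 3). Calcium sensitization had -0.14 with 0 of 20 called (adjusted p = 0.0461, then adjusted p = 0.307 with an estimated correlation); the adjusted p was 0.0584, 0.0811 and 0.0526 without control replicates 1, 2 and 3, 0.0578 without day 3 replicate 3 and 0.0861 without day 5 replicate 3.

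The other 14 lists tested on day 5 had no call. The lowest adjusted p among them were 0.0517 for lipid uptake and efflux, 0.0571 for dedifferentiated smooth muscle and 0.0601 for immediate early and heat shock genes. Matrix proteases and inhibitors had 4 higher and 1 lower of 19 (adjusted p = 0.0693). Some of these lists had a call in other settings: dedifferentiated smooth muscle with the slide as a block (adjusted p = 0.0445), fry (0.0384) and the mean of all probes of a gene (0.0312), and lipid uptake and efflux with fry (0.0384) and the mean of all probes (0.0376). Matrix proteases had one with fry (0.0384), and immediate early and heat shock genes were called lower with normexp (0.0015). The median, the mean and the test differed in sign for neutrophils (0.04, 0.07 and a lower rank), vasoconstrictor systems (0.03, 0.04 and lower), TGF-beta and BMP signalling (0.05, 0.01 and lower), vasodilator systems (-0.05 and a mean of 0.01) and glycolysis and hypoxia (-0.09 and a mean of 0.04), all without a call. EDNRA changed by -0.02 (adjusted p = 0.975), EDN1 by -0.15 (adjusted p = 0.849) and HBA by 0.97 (adjusted p = 0.407). Of the vasoconstrictor genes, ADRA2A was called higher, with log2 changes of 2.703, 2.066 and 0.7 on the slides. That call ended without 8 of the 12 arrays in turn (limma adjusted p = 0.0501 to 0.152).

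In total 533 probes changed on day 5, 471 higher and 62 lower (limma), naming 162 genes, 146 higher and 16 lower. Of the 533 probes, 530 had the same direction on all 3 slides, which their selection on these arrays largely sets. The count of called probes was 280, 315 and 324 without day 5 replicate 1, 2 and 3. It was 221 with normexp background correction, 345 with no filter on dim probes, 311 among probes above background on all 12 arrays, 210 on the 6 arrays compared alone and 1368 with array weights. With normexp background correction the log2 change was 2.53 for CRYBA4, 1.72 for SLC15A2, 2.12 for ABCA6, 1.26 for CDK1, 0.90 for NDC80, 1.23 for CD68 and 1.39 for HMOX1. Calls ended with it for NCAPG (adjusted p = 0.0537), SGPL1 (0.119), MPEG1 (0.0742), RGCC (0.826) and TENM1 (0.226). On the 6 arrays alone they ended for HP (0.0715), COL1A1 (0.0595), COL1A2 (0.0525) and RLN1 (0.0872), and for RLN1 also with no filter on dim probes (0.0686) and with an intensity trend (0.053). With fry, the lists of cytokines, lymphocytes, calcium sensitization and antigen presentation (adjusted p = 0.123 each) and of endothelial genes (0.2) had no call.

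On day 7, macrophage and complement genes had the smallest adjusted p of the lists that rose, and the lists of contractile smooth muscle and endothelial genes fell. With an estimated correlation no list of that day kept a call, with an adjusted p of 0.0767 for macrophage, 0.1 for complement, 0.193 for contractile smooth muscle and 0.203 for endothelial genes. CRYBA4 rose 23.6-fold, to 2.34 ± 0.41 from -2.22 ± 0.69 (SD, n = 3 each), SLC15A2 17.3-fold and SAA3 16.3-fold, to 7.04 ± 0.58 from 3.01 ± 1.16. MMP9, a gelatin-degrading metalloproteinase, fell by 2.41 on the log2 scale, to -1.66 ± 0.58 from 0.76 ± 0.59 (SD, n = 3 each).

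By the fit, CRYBA4 rose by 4.56 (SE 0.48, adjusted p = 0.000846), SLC15A2 by 4.12 (SE 0.46, adjusted p = 0.00123), SAA3 by 4.02 (SE 0.52, adjusted p = 0.003), HP by 3.499 (SE 0.55, adjusted p = 0.00863) and ABCA6 by 3.37 (SE 0.49, adjusted p = 0.00578). On the 3 slides SAA3 changed by 4.997, 4.803 and 2.269. SGPL1 was at least 2.58-fold higher (adjusted p = 0.00212) and NCAPG at least 1.88-fold higher (adjusted p = 0.000807). MMP9 changed by -1.40, -2.32 and -3.52 on the slides (SE 0.33, adjusted p = 0.00441). RSPO1 fell by 1.49 (SE 0.21, adjusted p = 0.00443; slides -1.45, -1.19 and -1.84). RLN1 rose by 4.82 (SE 0.98, adjusted p = 0.0282), a call that ended without control replicate 1 (adjusted p = 0.106), control replicate 2 (0.0977), day 7 replicate 2 (0.0757) and day 7 replicate 3 (0.103). BPI, a protein of neutrophil granules that kills bacteria, rose by 3.10 (SE 0.63, adjusted p = 0.0291, above background in 1 of 3 controls), a call that ended without control replicate 1 (adjusted p = 0.0751), control replicate 2 (0.0709), day 7 replicate 1 (0.111) and day 7 replicate 3 (0.0745). CX3CR1, the fractalkine receptor of microglia and monocytes, fell by 1.62 (SE 0.35, adjusted p = 0.0384), and without control replicate 1, control replicate 2, day 5 replicate 2 or day 7 replicates 1, 2 or 3 the adjusted p was 0.125, 0.0791, 0.0592, 0.106, 0.06 or 0.14. Its lower level was not particular to day 7. On day 3 the log2 values of CX3CR1 were -3.136, -4.117 and -4.11, against -1.459, -1.829 and -1.62 in the controls.

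Of 12 macrophage genes, 8 rose on day 7 (10 adjusted over the list alone), with a list median of 1.59 (slides 1.56, 1.74 and 1.53; adjusted p = 2.25e-11, then adjusted p = 0.0767 with an estimated correlation and 6.37e-11 with the slide as a block). CD68 rose 3.99-fold (adjusted p = 0.000618), MRC1 4.11-fold (adjusted p = 0.00578). MPEG1 was at least 3.90-fold higher (adjusted p = 0.000807). Of 15 complement genes, 7 rose (13 and 1 lower adjusted over the list alone), with a median of 1.14 (slides 0.67, 1.18 and 1.25; adjusted p = 2.92e-09, then adjusted p = 0.1 with an estimated correlation and 1e-08 with the slide as a block). C1R rose 3.12-fold (adjusted p = 0.000618). Of 29 cell cycle genes, 9 rose (16 and 2 lower adjusted over the list alone), with a median of 0.72 (slides 1.02, 0.75 and 0.83; adjusted p = 3.2e-09, then adjusted p = 0.1 with an estimated correlation and 2.57e-08 with the slide as a block). With the 9 members that no control measured well above background at their bound, the cell cycle median was 0.43, and bounds gave 1.06 for complement. CDK1 rose 6.29-fold (adjusted p = 0.00142) and NDC80 4.85-fold (adjusted p = 0.000618). Of 11 interferon response genes, 4 rose (10 adjusted over the list alone), with a median of 1.24 (slides 1.08, 1.45 and 1.37; adjusted p = 1.24e-08, then adjusted p = 0.16 with an estimated correlation and 2.92e-07 with the slide as a block). Of 13 genes of heme, iron and oxidative stress, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.72 (slides 0.94, 0.95 and 0.28; adjusted p = 9.53e-06, then adjusted p = 0.16 with an estimated correlation and 7.96e-06 with the slide as a block). HMOX1 rose 6.99-fold (adjusted p = 0.00332) and FTL, the light chain of the iron store ferritin, 2.61-fold (adjusted p = 0.00936). TFRC was the member that fell, at -1.20 (adjusted p = 0.0444), and without each array other than control replicate 3 and day 3 replicates 1 and 2 its adjusted p was 0.0527 to 0.136.

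Other lists rose on day 7 with few members called. Extracellular matrix genes had a median of 0.42 with 3 of 25 called (7 adjusted over the list alone; adjusted p = 0.000139, then adjusted p = 0.249 with an estimated correlation; 0.065 without control replicate 3). COL1A1 rose 2.97-fold (adjusted p = 0.00578). Dedifferentiated smooth muscle genes had 0.60 with 3 of 11 called (4 adjusted over the list alone; adjusted p = 0.0297, then adjusted p = 0.23 with an estimated correlation; 0.0656 without control replicate 2). The members called were LGALS3, CD44 and LUM, whose calls ended without 5, 2 and 10 of the 12 arrays in turn. MYH10, a fixed gene of that list, changed by -0.176, 0.294 and -0.446 on the slides, without a call. LUM is also in the fibroblast and leptomeninges list, and which cells carried these rises was not tested. Lipid uptake and efflux had 0.72 with 2 higher and 1 lower of 13 (6 and 2 adjusted over the list alone; adjusted p = 0.0213, then adjusted p = 0.202 with an estimated correlation; 0.137 without control replicate 3). Fibroblast and leptomeninges genes had 0.71 with 1 of 11 called (5 adjusted over the list alone; adjusted p = 0.0372, then adjusted p = 0.43 with an estimated correlation), and without control replicates 1 and 2 or day 7 replicates 1 and 3 the adjusted p was 0.0918, 0.0687, 0.0662 and 0.0758. The unfolded protein response had 0.25 with 0 of 12 called (adjusted p = 0.0438, then adjusted p = 0.502 with an estimated correlation). Its adjusted p was 0.0567, 0.0818 and 0.0789 without control replicates 1, 2 and 3, 0.12 without day 7 replicate 1 and 0.103 with quantile normalization.

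Of 25 contractile smooth muscle genes, 0 had a call on day 7 (5 lower adjusted over the list alone), and the list fell with a median of -0.53 (slides -0.54, -0.38 and -0.52; adjusted p = 1.25e-05, then adjusted p = 0.193 with an estimated correlation and 3.34e-06 with the slide as a block). Endothelial genes fell as a list with a median of -0.70 and 0 of 10 called (4 lower adjusted over the list alone; slides -0.90, -0.31 and -0.52; adjusted p = 0.00162, then adjusted p = 0.203 with an estimated correlation). Calcium sensitization had -0.18 with 1 of 20 called (2 adjusted over the list alone; adjusted p = 0.0389, then adjusted p = 0.249 with an estimated correlation), and 0.0687, 0.065 and 0.0871 without control replicate 2, control replicate 3 and day 7 replicate 3. Ion channels and calcium handling had -0.23 with 0 of 28 called (adjusted p = 0.0438, then adjusted p = 0.202 with an estimated correlation), and 0.0818, 0.065, 0.0846 and 0.0846 without control replicates 2 and 3 and day 7 replicates 1 and 3. ACTA2 changed by -0.62 (adjusted p = 0.236), MYH11 by -0.80 (adjusted p = 0.195), EDNRA by 0.03 (adjusted p = 0.928) and NOS3 by -0.96 (adjusted p = 0.15). HBA changed by 1.40 (adjusted p = 0.164) and HBB2, a beta globin, by 1.48 (adjusted p = 0.2); 2 of the 3 erythroid genes were called higher adjusted over the list alone and 0 over all probes. The other 13 lists tested had no call, with oxidative phosphorylation at an adjusted p of 0.0848, or 0.00479 with the slide as a block, and neutrophils at 0.326. Immediate early and heat shock genes were called lower with normexp (adjusted p = 0.0473). Lymphocyte genes had a median of 0.05, a mean of -0.14 and a lower rank in the test (adjusted p = 0.94).

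In total 597 probes changed on day 7, 491 higher and 106 lower (limma), naming 192 genes, 149 higher and 43 lower. Of the 597 probes, 594 had the same direction on all 3 slides, which their selection on these arrays largely sets. With the slide as a block the count of called probes was 954. It was 311, 362 and 1692 without control replicate 1, 2 and 3, and 229, 332 and 239 without day 7 replicate 1, 2 and 3. It was 253 with normexp background correction, 305 with no filter on dim probes, 292 on the 6 arrays compared alone and 1388 with array weights. With normexp background correction the log2 change was 2.22 for SLC15A2, 1.58 for HMOX1, 1.07 for CDK1, 0.73 for NDC80 and -1.49 for MMP9. Calls ended with it for SGPL1 (adjusted p = 0.266), NCAPG (0.203), MPEG1 (0.093), BPI (0.0514) and CX3CR1 (0.298). They ended on the 6 arrays alone for COL1A1 and FTL (0.0518 each) and RLN1 (0.0835), with no filter on dim probes for RLN1 (0.0657), BPI (0.0688) and CX3CR1 (0.0915), and with the slide as a block for CX3CR1 (0.0567). With fry, the lists of endothelial (0.0534), fibroblast and leptomeninges (0.0679), calcium sensitization (0.0583) and unfolded protein response genes (0.138) had no call, nor had the last with the mean of all probes of a gene (0.0569).

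**Figure D3:**
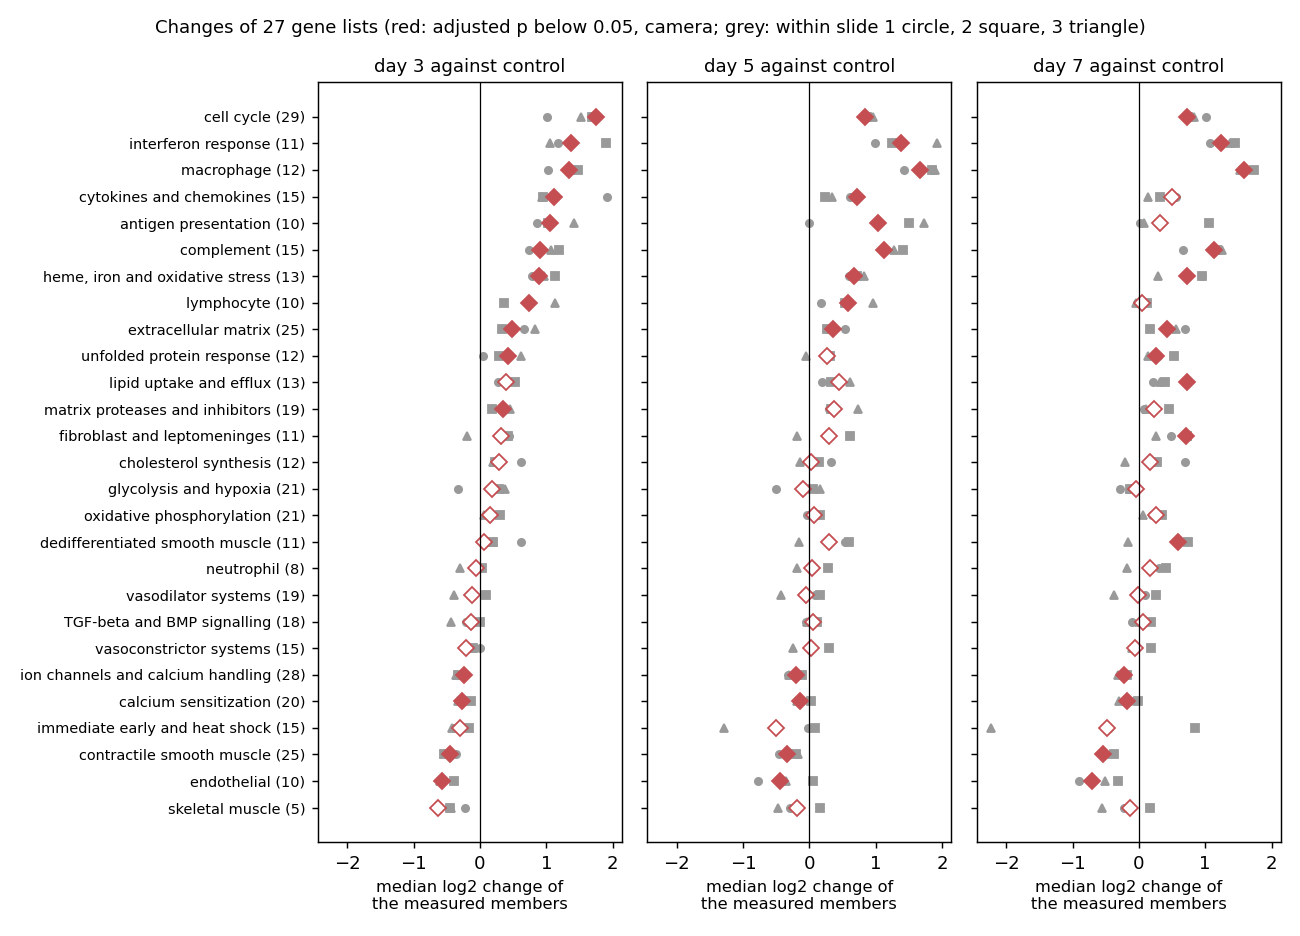
Median fitted log2 change against the controls of the measured members of each gene list shown, on days 3, 5 and 7, with 1 small grey symbol per slide and filled diamonds where the list was called. The cell cycle list has medians of 1.75, 0.84 and 0.72, the macrophage list 1.35, 1.67 and 1.59, and the contractile smooth muscle list -0.45, -0.34 and -0.53.

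Many of the same genes were called on several days. On all 3 days 96 genes were called higher and 6 lower, the latter ERBB2, MTHFD2, PDZD2, PPFIBP2, RSPO1 and SOX1, named because they are so few, after their values were seen. Of these only RSPO1 kept its call on all 3 days without each array. Days 3 and 5 shared 399 of the probes called higher, where independent lists of those sizes would share 22.2, days 3 and 7 shared 397 (23.1) and days 5 and 7 shared 372 (8.7). Of the probes called lower, days 3 and 5 shared 44 (1.2), days 3 and 7 shared 60 (2) and days 5 and 7 shared 26 (0.2). The log2 changes of these pairs of days correlated across probes at 0.836, 0.758 and 0.863, against 0.498, 0.499 and 0.501 in simulated data with no effect, and their covariance was 0.285, 0.255 and 0.237 against 0.0427, 0.0429 and 0.0429. The 3 controls are shared by all these comparisons and are too few to be divided into sets of at least 2 arrays, so part of the excess may come from them. The simulation also gave a probe the same spread in every group. The lowest correlation within a group was 0.964, in the controls, so shared controls alone could give more than the simulated values. For the mean of the 3 days against the controls, 1849 probes changed, 1329 higher and 520 lower, with 820 without control replicate 1 and 929 without control replicate 2. It was 899 with normexp background correction and 1118 with no filter on dim probes. By the F test, 782 probes differed between any day and the controls, with 405 without control replicate 1, 453 with no filter on dim probes and 1320 with array weights.

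Tested directly against each other, the days after the bleed differed in few probes, led by CCK. Its log2 change between day 3 and day 5 was -4.76 (SE 0.46, adjusted p = 0.00973; slides -3.81, -4.59 and -5.88), and between day 3 and day 7 it was -5.08 (SE 0.46, adjusted p = 0.0025; slides -3.95, -5.31 and -5.98). CCK stood at 1.67 ± 1.06 on day 3 and at -3.21 ± 0.45 in the controls, -3.09 ± 0.20 on day 5 and -3.40 ± 0.55 on day 7 (SD, n = 3 each). Between day 3 and day 5, 3 probes changed, all lower on day 5, and CCK was the only named gene; its call ended without day 5 replicate 3 (adjusted p = 0.0595) and on the 6 arrays alone (0.185). With normexp background correction the changes of CCK were -2.45 and -2.66. That count was 5 without control replicate 2, 5 without day 3 replicate 1, 0 without day 5 replicate 3, 56 with normexp background correction, 0 on the 6 arrays compared alone and 861 with array weights. Between day 5 and day 7, limma called 0 probes, with 414 at an unadjusted p below 0.05.

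Between day 3 and day 7, 38 probes changed, 11 higher and 27 lower on day 7, naming 9 genes. All 38 had the same direction on all 3 slides, which their selection on these arrays largely sets. TIMP1 was lower on day 7 than on day 3 by a log2 change of -2.01 (adjusted p = 0.045), MMP9 by -2.17 (adjusted p = 0.0467) and CDC20, an activator of the anaphase-promoting complex, by -1.64 (adjusted p = 0.0467). COL6A5, a collagen VI chain, was at least 1.38-fold lower on day 7 (adjusted p = 0.0467), where 2 of 3 day 3 arrays and no day 7 array measured it. LRRC17, a leucine-rich repeat protein, was higher by 1.85 (adjusted p = 0.0467). BUB1B (-1.61), CD1D (-1.12) and ESM1 (-1.501) were also lower (adjusted p = 0.0467 each), CD1D presenting lipids to T cells and ESM1 being secreted by endothelial cells; CD1D and ESM1 were named after their values were seen. With the slide as a block the count was 2 and only CCK among the named genes kept a call. Without 1 array the count was 4 for control replicate 1, 70 for control replicate 2, 4 and 3 for day 3 replicates 2 and 3, 4, 4 and 3 for day 5 replicates 1, 2 and 3, and 6, 2 and 2 for day 7 replicates 1, 2 and 3; the calls of the genes other than CCK then ended in 9 or 10 of the 12 cases, with adjusted p up to 0.226. The count was 3 with no filter on dim probes, 12 on the 6 arrays compared alone, 280 with array weights and 20 in the authors' value table.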

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

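The tests of technical explanations, the regroupings of the arrays and the list tests between day 7 and day 3 were chosen only after the results were seen. Every result listed here stands out because the change from the controls differed between 2 days by a direct test of those days. Groups of 3 arrays were not tested for outliers.

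Between day 5 and day 3, 3 probes changed, with CCK at a log2 change of -4.76. Between day 7 and day 3, 38 probes changed, with CCK at -5.08, COL6A5 at a fitted -2.72 (at least 1.38-fold lower, as no day 7 array measured it), MMP9 at -2.17, TIMP1 at -2.01, CDC20 at -1.64 and LRRC17 at 1.85. With the slide as a block that count was 2 and only CCK of these genes kept a call, and without 1 array it ranged from 2 to 70. The cell cycle list was lower on day 7 than on day 3, with a median of -0.85 (slides -0.37, -0.98 and -0.93; adjusted p = 1.79e-12, then adjusted p = 0.119 with an estimated correlation and 2.13e-12 with the slide as a block). The cytokine and chemokine list was lower with a median of -0.74 (slides -0.99, -0.16 and -1.62; adjusted p = 0.000122, then adjusted p = 0.317 with an estimated correlation and 0.000109 with the slide as a block). The lymphocyte list was lower with a median of -0.75 (slides -0.79, -0.38 and -0.87; adjusted p = 0.000984, then adjusted p = 0.317 with an estimated correlation and 3.71e-05 with the slide as a block). The antigen presentation list was lower with a median of -0.59 (adjusted p = 0.00639, then adjusted p = 0.561 with an estimated correlation, and 0.0816 without day 3 replicate 3). The list of matrix proteases and inhibitors was lower with a median of -0.17 (adjusted p = 0.0181, then adjusted p = 0.317 with an estimated correlation). The list of heme, iron and oxidative stress was lower with a median of -0.30 (adjusted p = 0.0202, then adjusted p = 0.561 with an estimated correlation, 0.0731 without day 3 replicate 3 and 0.0521 without day 7 replicate 2). The fibroblast and leptomeninges list was higher with a median of 0.39 (adjusted p = 0.0227, then adjusted p = 0.561 with an estimated correlation, and 0.0785, 0.0641 and 0.0627 without day 3 replicate 2, day 7 replicate 1 and day 7 replicate 3). Slide medians were uneven: -0.582, -0.019 and -1.317 for antigen presentation and -0.241, -0.022 and -0.166 for matrix proteases and inhibitors. They were -0.07, -0.144 and -0.622 for heme, iron and oxidative stress and 0.035, 0.304 and 0.666 for fibroblasts and leptomeninges.

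The macrophage, complement and cell cycle lists were higher on each day, and 3 technical explanations were weighed. With an estimated correlation the calls of macrophage (0.0827) and complement (0.109) ended on day 3, and those of macrophage (0.0767), complement (0.1) and cell cycle (0.1) on day 7. A lower share of smooth muscle would raise all other cell types alike. The macrophage list mean rose more than the endothelial list mean by 1.97 on the log2 scale (exact permutation p = 0.00455, two-sided, not kept to the slides). This is the lowest p that 220 rearrangements allow, and these lists had already been called in opposite directions. The test therefore does not decide the question, though the endothelial list mean itself did not rise (change of -0.49). Blood carried with the artery would raise neutrophil genes too. The macrophage list mean rose more than the neutrophil list mean by 1.34 (exact permutation p = 0.00455). The macrophage list was already known to be called and the neutrophil list not, so this test does not decide the question. The erythroid list, too small to test, had medians of 0.07, 0.97 and 1.40 on days 3, 5 and 7. HBA of red blood cells had a change of 1.40 on day 7 without a call (limma adjusted p = 0.164), and blood stays open. Array position on the slide stays open, because each group had the same position on 3 of 3 slides. Entry of macrophages into the artery or activation of resident ones could give the same values and was not tested here.

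The falls of transporter and leptomeningeal genes on day 3, among them SLC22A6 and PTGDS, were weighed against 2 explanations. Of 7 such genes, 7, 4 and 4 kept a call without day 3 replicate 1, 2 and 3, and each kept at least 0.876 of its log2 change. The genes had been named for arrays that do not overlap, so neither count nor share decides whether one day 3 array carried the falls, and this stays open. Less leptomeningeal tissue on the day 3 arteries would lower that list, yet 7 of its 11 measured genes had a higher mean on day 3 (exact sign p = 0.549), which leaves it open.

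The grouping of the arrays was tested by regrouping them. Each comparison of 2 groups has only 10 splits, too few for a share under 0.05, so only the counts are given. For day 3 against the controls the true split gave 1754 probes and the highest other 1, with 1 split of 10 reaching the true count. For day 5 it gave 533 and the highest other 0 (1 of 10), and for day 7 597 and 0 (1 of 10). Between days 5 and 3 it gave 3 and 0 (1 of 10), between days 7 and 3 38 and 0 (1 of 10), and between days 7 and 5 0, as in all 10 splits. For any day against the controls, 782 probes stood against at most 562 in the other splits (1 of 100). That 562 came from a split that kept the 3 controls together and mixed only the days, as 5 of the 100 did with the true one, and splits with the controls apart gave at most 12. For the mean of the 3 days 1849 stood against at most 476 (1 of 100), in the split that set control replicate 3, day 5 replicate 3 and day 7 replicate 3, all of slide 3, against the other arrays. The regroupings did not keep to the slides.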

How the results depend on the processing

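No left-out array and no setting was chosen after the results were seen. Counts of calls moved with the processing. Of 315 results for named genes, 185 were called, and 63 of these 185 were the same in every alternative that gave a value for them. The filter for all 12 arrays gave one for 215 of the 315. Of the results for named genes 2 reversed, and 1 of those for lists, and genes without a call changed sign in 56 cases, which are not counted as reversed. With normexp background correction the counts were 1007 on day 3, 221 on day 5, 253 on day 7, 899 for the mean of the days and 56 between days 5 and 3. With no filter on dim probes they were 974, 345, 305 and 1118, with 3 between days 7 and 3 and 453 by the F test. With probes above background on all 12 arrays only, day 5 gave 311 and days 5 and 3 differed in 0. On the 6 arrays compared alone the counts were 897, 210 and 292, with 0 between days 5 and 3 and 12 between days 7 and 3. Array weights gave 1368 on day 5, 1388 on day 7, 861 between days 5 and 3, 280 between days 7 and 3 and 1320 by the F test, and moved the share of higher calls from 88.4% to 70.5% on day 5 and from 82.2% to 64.1% on day 7. That share moved in other settings too. On days 5 and 7 it was 71.88% and 75.74% with no filter on dim probes, and 82.04% and 67.61% without control replicate 3. On the 6 arrays compared alone it was higher, 93.33% and 87.33%. The balance of rises and falls thus depends on the processing and on the controls. An intensity trend gave 6 between days 5 and 3, and in the values of the authors' table days 7 and 3 differed in 20. At an adjusted p below 0.01 the counts were 549, 186, 186 and 570, 1 and 2 between days 5 and 3 and days 7 and 3, and 269 by the F test, and a 2-fold minimum left 926 for the mean. A stricter limit lowers a count by construction, and elsewhere the cause was not tested.

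Without 1 array the count ranged from 789 to 1943 on day 3, 280 to 685 on day 5, 229 to 1692 on day 7, 820 to 2617 for the mean, 0 to 5 between days 5 and 3, 2 to 70 between days 7 and 3 and 405 to 861 by the F test. The number of lists called on day 5 ranged from 8 to 15. With an estimated correlation 1, 3 and 0 lists kept a call on days 3, 5 and 7, of 15, 13 and 14. Under normexp 3 results turned on day 5. PHGDH, called lower at -1.25, had a change of 0.076, and PFN4, called lower at -1.22, one of 0.152. The list of oxidative phosphorylation, which had no call (adjusted p = 0.976), was called lower (adjusted p = 0.0015). The cause was not tested.

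Arrays that share a replicate number share a slide. Of 18 such pairs, 10 had a correlation of deviations above 0.1 (mean 0.106, from -0.153 to 0.387). The 36 other pairs had a mean of -0.052, a value that centring on the group means ties to the first. The main fit left the slide out, but these values do not exclude a slide effect. With the replicate block the counts were 2281, 662 and 954 on days 3, 5 and 7 and 2390 for their mean. Without it they were 1754, 533, 597 and 1849. The block gave 2 between days 5 and 3, 0 between days 7 and 5, 2 between days 7 and 3 and 930 by the F test. Without it these were 3, 0, 38 and 782. Signal near background limits the dim probes: 50.1% to 64.0% of spots were well above it.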

Other observations

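The tests in this part were chosen only after the results were seen. Solute carrier genes, which move ions, nutrients and drugs across membranes, were overrepresented among the falls on day 3. Of 149 measured solute carrier genes, 9 fell (6.04%), against 143 of 7233 other genes (1.98%; Fisher's exact p = 0.00353, two-sided, odds ratio 3.19). Of the same genes 8 rose (5.37%), against 4.91% of the others (Fisher's exact p = 0.703). The genes called lower included SLC22A6, SLC16A12 at -1.81 (adjusted p = 0.00605) and SLC5A3, a carrier of inositol, at -1.02 (adjusted p = 0.00546), which kept their calls without each array. Other calls counted here did not: SLC22A8 had an adjusted p of 0.0504 without day 3 replicate 2, and SLC44A5 had 0.0858, 0.0556, 0.0853 and 0.0974 without control replicates 1 and 2 and day 3 replicates 2 and 3, and 0.0587 with no filter on dim probes. SLCO1A2 had 0.0989 with normexp background correction. Genes are not independent of each other, so this p may be too small.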
